A study of Mus musculus with 10 samples.

How the data were processed

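RNA sequencing was carried out on 10 libraries of sorted mouse Treg cells in 5 groups of 2. Per the labels' protocols, cells came from pooled spleens and peripheral lymph nodes, CD8 and CD19 positive cells were depleted, and the rest was stained for CD4, TCRβ, CD62L, ICOS and TIGIT and sorted with the YFP reporter of Foxp3. The gates that define naive, activated and effector cells are not given in the sources used here. Each biological replicate pooled RNA of up to 4 independent sorts, and libraries were made with an Illumina TruSeq RNA kit, per the labels' protocols. Genes whose products were stained or depleted (Sell, Icos, Tigit, Cd4, Foxp3, Cd8a, Cd8b1, Cd19) were set by the sort and are not findings.

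The authors deposited 1 table of raw counts per gene for all libraries, with 27179 Entrez genes and a column of gene lengths in bases. Per the submitters' processing notes the authors used Subread, featureCounts and limma with the builds GRCm38 and mm10, and no versions are given. Whether the counts were made with regard to strand is not given in the sources used here, so reads of overlapping and antisense genes cannot be assigned to one of them. The counts hold whole numbers that sum to 14113839 to 28632234 per library in the deposited table, and a pool of RNA from several sorts lies behind each of them. The authors also deposited 1 file of log2 RPKM values per library with 13547 genes. How these log2 values were normalised and which offset was added is not given in the sources used here; after the gene length is removed, the 10 libraries have nearly the same distribution. The other column of the deposited table, gene length, was used only for that check. Each log2 RPKM file matched its own count column best, in 10 of 10 libraries. Gene symbols were taken from the files (25613 genes with a symbol, 1566 without), coordinates from a RefSeq gene table of GRCm38.p6, to which 25275 gene identifiers matched. The reference assembly has the same chromosome coordinates as the build of the files.

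The groups were taken from the labels. Genes were kept by edgeR's filterByExpr on the 5 groups (minimum count 10, minimum total count 15), which left 13714 genes with 99.97% of all counts; the other 13465 genes were not tested. Library sizes were scaled by TMM. A single fit of edgeR 4.0.16 (quasi-likelihood, robust) in R 4.3.3 covered all libraries with a mean per group and no block, and the groups shared 1 estimate of the spread with 5 residual degrees of freedom. The tests were two-sided F-tests with Benjamini-Hochberg adjustment and a threshold of 0.05. There were 7 comparisons: activated against naive, effector against activated and effector against naive cells of the wild type, labelled Myb knockout against wild type in naive and in activated cells, activated against naive cells labelled Myb knockout, and the interaction of activation with the genotype. Fold changes are on the log2 scale with standard errors, and group levels are means of CPM with SD over 2 libraries. Each standard error (SE) was derived from the test, as the absolute log2 fold change divided by the square root of F. With groups of 2, regrouping the samples cannot give a share under 0.05, so no such test was run.

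A value of 3 counts equals 0.213 CPM in the smallest library before TMM scaling, and a level under it was not read as expression. Counts of reads are not independent molecules, so this limit covers counting error only. Between the 2 libraries of a group the counts differed by more than sampling noise, with a chi-square per gene of 8.94 to 164 over the 5 groups, so no library was counted as a copy of another.

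The 25 gene lists were fixed before the data were examined, as were the comparisons, the settings to be tried and the rule for named genes. The lists cover Treg identity, naive and resting T cells, effector Treg cells, homing, proliferation, apoptosis, NF-kB and costimulation, immediate early genes, inhibitory receptors, helper lineages and cytokines, glycolysis, cholesterol synthesis, oxidative phosphorylation, the interferon response, endoplasmic reticulum stress, the Myb family, sort markers, and markers of B cells, plasma cells, CD8 T cells, natural killer and innate lymphoid cells, myeloid cells, dendritic cells, erythroid cells and platelets, and stroma and endothelium. Of 410 entries 408 matched a gene of the count table. The 23 lists with at least 5 tested genes were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation between genes 0.01), 161 tests in all, with Benjamini-Hochberg adjustment over all of them. With camera's estimated correlation 0 of the 161 tests passed (smallest adjusted p = 0.672), against 51 with the preset correlation. Fry, which asks whether the genes of a list move one way and does not compare them with other genes, passed 23, of which 14 were among the 51. Sort genes are members of several lists besides that of sort markers (Foxp3 in Treg identity, Sell in naive and resting and in homing, Icos in effector Treg and in costimulation, Tigit in effector Treg and in inhibitory receptors, Cd19, Cd8a and Cd8b1 in those of other cells), and the counts given include them unless stated. The lists were therefore tested again without them. The members of a list that passed were counted over all tested genes and also when adjusted over the list alone.

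Genes named in the text followed a rule. In the comparisons of activated with naive and effector with activated wild type cells and in both comparisons of the genotypes, these were up to 12 rises and 12 falls with the largest log2 fold change among genes past the threshold, with a mean of at least 3 log2 CPM and no overlap between the libraries of the groups. In the others they were up to 5 each. Predicted genes, Riken clones and genes without a symbol were left out. Myb and 11 marker genes were looked at in every comparison, and list members with the smallest adjusted p, up to 4 per list and direction, served as examples.

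Overlaps of calls between comparisons without a library in common were tested with two-sided Fisher exact tests over the 13714 genes, adjusted over the 12 overlaps. The 200 genes most raised and the 200 most lowered in effector against naive wild type cells were tested with camera in the comparison of activated cells. Settings tried were DESeq2 size factors and upper-quartile scaling in place of TMM, the Wald test of DESeq2 1.42.0, limma voom, no filter on low counts, a CPM of at least 5 in 2 libraries, only the groups compared, the replicate number as a block, a fold of at least 2, an adjusted p under 0.1 for the overlaps, and each of the 10 libraries left out in turn. Limma on the authors' log2 RPKM values, removal of ribosomal RNA genes, and removal of libraries with Y-linked reads or of wild type naive library 2 as well were added later, as was the test of the lists without sort genes.

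The tests were checked on simulated counts for the real 13714 genes with 200 of them changed, 100 by 2-fold and 100 by 4-fold. Of the 2-fold changes 73 were recovered in activated against naive wild type cells, 65 in effector against activated cells, 64 and 67 in the comparisons of the genotypes in naive and activated cells, and 62 in activation of cells labelled Myb knockout. Of the 4-fold changes 79, 82, 81, 85 and 89 were recovered in the same order, with 8, 11, 10, 10 and 9 false calls. In simulated libraries with 3 lists shifted by 0.7 on the log2 scale the 3 lists were called in each of these comparisons. In effector against activated cells 2 further lists were called, and none in the others. The simulated genes varied independently of each other, without a shift shared by many genes of a library such as that of wild type naive library 2. The shares recovered and the list calls therefore do not carry over to comparisons with such a shift or with correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.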

Results

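Regulatory T (Treg) cells are CD4 T cells that express the transcription factor Foxp3 and restrain immune responses. RNA was sequenced from Treg cells sorted out of pooled spleens and peripheral lymph nodes of healthy adult C57BL/6 mice, with the mesenteric nodes left aside. The series asks what Myb, a transcription factor best known from blood cell progenitors, does in the formation of effector Treg cells. By their labels the 10 libraries fall into 5 groups of 2: naive, activated and effector cells of wild type females, and naive and activated cells of females in which a Cre recombinase expressed from the Foxp3 locus acts on floxed Myb alleles. No effector library of the second genotype was analysed here. The wild type females carried the Cre allele on both X chromosomes and the others on a single X chromosome, so their Treg cells developed beside Treg cells without Cre. The Myb genotype and this mosaic setting therefore change together in each comparison between the genotypes. Each library is a biological replicate that pools RNA of up to 4 sorts.

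Total counts were 28632234 and 21369804 in the naive, 27262076 and 23264542 in the activated, and 19853914 and 24531748 in the effector libraries of the wild type. They were 16593428 and 26967885 in the naive and 14113839 and 19085961 in the activated libraries labelled Myb knockout. A single count was worth 0.0709 CPM (counts scaled to the total of each library) in the smallest library before TMM scaling. In the largest library it was worth 0.0349 CPM. The CPM values of genes and lists are scaled by TMM factors as well. The first principal component held 67.2% of the variance. It placed the wild type naive libraries at -58.7 and -9.84, the activated ones at 29.3 and 17.2 and the effector ones at 81.9 and 84.8. The libraries labelled Myb knockout lay at -77.1 and -79.9 for naive cells and at 19.7 and -7.44 for activated cells. Naive library 2 of the wild type correlated more closely across genes with activated library 2 (r = 0.993) than with naive library 1 (r = 0.983). Genes are not independent replicates, so these values only describe the libraries. Activated library 1 labelled Myb knockout held 7.34% of its counts in the ribosomal RNA precursor Rn45s, against 0.106% to 0.215% in the others.

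**Figure D1:**
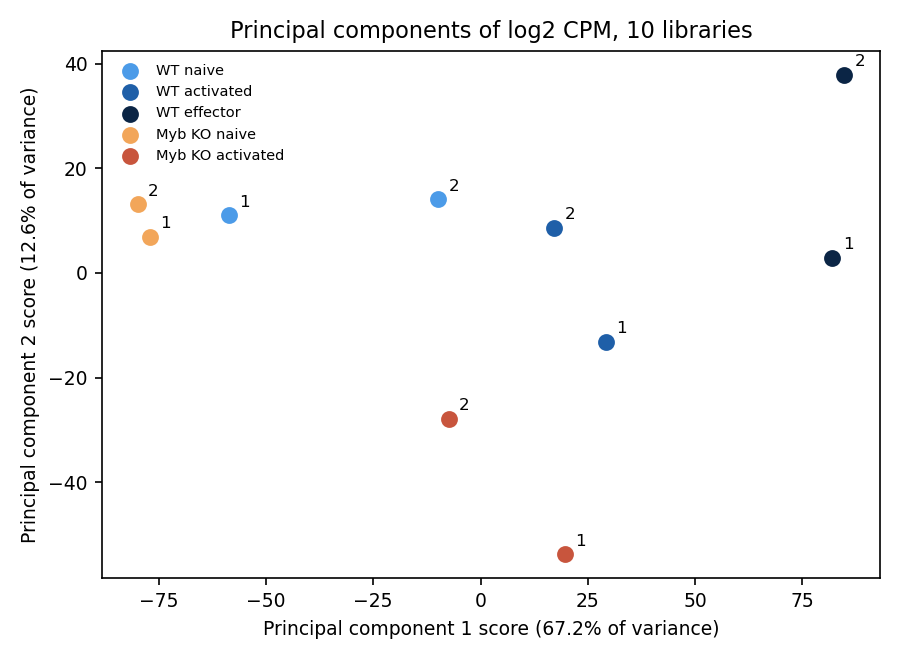
Principal components of the log2 CPM values of the 10 libraries, PC1 (67.2% of the variance) on the horizontal axis and PC2 (12.6%) on the vertical axis, with 1 point per library and colours for the 5 groups. Naive and effector libraries lie at opposite ends of PC1, and naive library 2 of the wild type lies apart from naive library 1.

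Myb (Entrez gene 17863, GRCm38 chromosome 10, start 21124930, end 21160984) was the targeted gene, and its counts were not found lower in the libraries labelled Myb knockout. It stood at 42.5 and 38.4 CPM in the naive, 25.4 and 34.8 in the activated and 20.8 and 38.9 in the effector wild type libraries. In the libraries labelled Myb knockout it stood at 39.3 and 41.5 CPM in naive and 43.3 and 56.3 CPM in activated cells. Both activated libraries labelled Myb knockout thus lay above both of the wild type. Over 22 other settings the log2 fold change of Myb between the genotypes in activated cells ran from 0.52 to 0.98. The group means in naive cells were 40.5 ± 2.94 CPM in the wild type and 40.4 ± 1.55 CPM in those labelled Myb knockout (SD, n = 2; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1). In activated cells the log2 fold change of Myb was 0.73 ± 0.30 (SE; edgeR adjusted p = 0.38). The counts add up all exons of a gene and the labels do not say which exons are floxed, so a transcript that lost only these exons would still be counted. The check of the labels by the level of Myb is therefore open, and the directions below refer to libraries labelled Myb knockout. Foxp3, the gene by which the cells were sorted, lay between 545 ± 41.2 and 565 ± 66.7 CPM (SD, n = 2) in the 5 group means. Among the wild type groups Myb did not pass the test either: its log2 fold change from naive to activated cells was -0.43 ± 0.29 (edgeR adjusted p = 0.464).

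**Figure D2:**
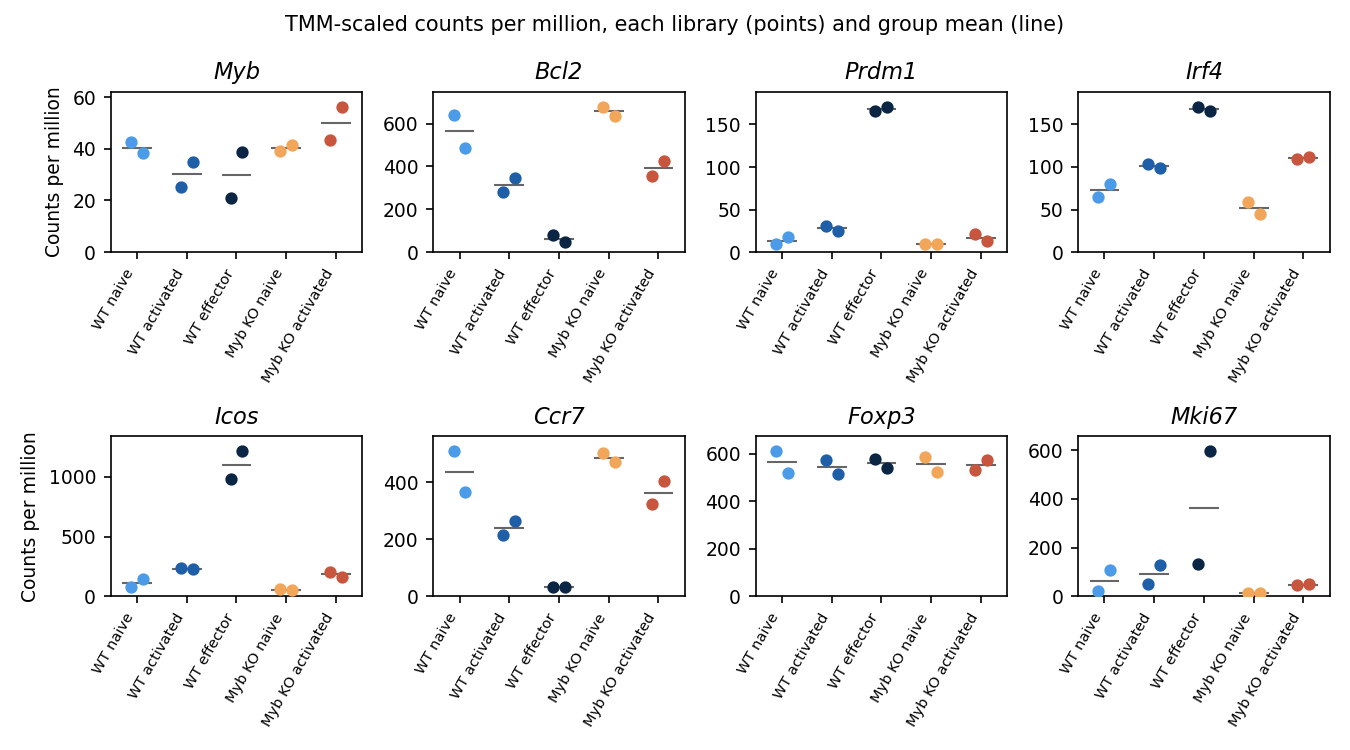
Expression of Myb, Bcl2, Prdm1, Irf4, Icos, Ccr7, Foxp3 and Mki67 in CPM (scaled by TMM factors), with 1 point per library and a line at each group mean of 2 libraries. Prdm1 and Irf4 are highest and Bcl2 and Ccr7 lowest in the effector libraries, while Foxp3 stays at a similar level in the 5 groups.

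The first comparison asked which genes separate effector from activated Treg cells of the wild type. Prdm1, which encodes the transcription factor Blimp-1 of differentiated effector Treg cells, rose from 28.3 ± 4.21 to 169 ± 3.45 CPM (SD, n = 2), a log2 fold change of 2.57 ± 0.33 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00469). Irf4, a transcription factor that acts with Blimp-1 in these cells, rose by 0.74 ± 0.13 (edgeR adjusted p = 0.00857), and the anti-inflammatory cytokine gene Il10 rose by 4.85 ± 0.80 (edgeR adjusted p = 0.012). Bcl2, which protects cells from apoptosis, fell by 2.33 ± 0.27 on the log2 scale, from 312 ± 44.4 to 62.4 ± 22.3 CPM (edgeR adjusted p = 0.00325). Ccr7, the chemokine receptor that guides naive T cells into lymph nodes, fell by 2.88 ± 0.19 (edgeR adjusted p = 5.16e-04). In all, 1840 of 13714 genes changed, 782 higher and 1058 lower in effector cells, and 574 of them by at least 2-fold.

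Of the 12 largest rises among genes with a mean of at least 3 log2 CPM and no overlap between the groups, Neb led with 3.65 ± 0.30; it encodes the muscle protein nebulin. It was followed by Prdm1, by Gcnt1 (2.31 ± 0.32), which encodes a glycosyltransferase that makes selectin ligands, and by the chemokine receptor gene Ccr8 (2.24 ± 0.27). The integrin chain gene Itgae (1.96 ± 0.43) and the inhibitory receptor gene Lag3 (1.80 ± 0.45) were also among them, as were Arl5a, Gpr55, Lgmn, Plxnd1, Kctd12 and the sort gene Icos. The largest fall was that of Igfbp4 (-7.88 ± 0.61), which encodes a binding protein of insulin-like growth factors and went from 121 ± 56.4 to 0.522 ± 0.23 CPM. Sorcs2 (-5.97 ± 0.56), Ly6c1 (-5.85 ± 0.58), Treml2 (-4.24 ± 0.31) and Gata1 (-3.85 ± 0.29) came next, followed by Sell, Gsta4, Dapk1, Adcy6, Arhgap20, Tdrp and St8sia1. Sell encodes CD62L. CD62L, ICOS and TIGIT were stained for the sort, so differences in Sell, Icos and Tigit follow from the gating and are not findings.

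The list of naive and resting T cell genes fell as a group: 16 of its 18 measured members fell, none rose and 2 did not pass (camera adjusted p = 1.27e-13; adjusted p = 0.672 with an estimated correlation). Besides Ccr7 and Bcl2, the transcription factor gene Tcf7 (-1.32 ± 0.15) and the actin cross-linker gene Actn1 (-2.40 ± 0.20) were among the members that fell. Adjusted over the list alone, 16 fell as well. Of the 30 genes of the effector Treg list 12 rose and 0 fell (camera adjusted p = 6.41e-10; adjusted p = 0.672 with an estimated correlation), and 21 rose when adjusted over the list alone. These lists include sort genes, Sell in the first and Icos and Tigit in the second. Without them 15 of 17 naive and resting genes fell (camera adjusted p = 1.16e-12) and 11 of 28 effector Treg genes rose (camera adjusted p = 3.59e-09). The Treg identity list moved in both directions, with 6 genes higher, 3 lower and 6 not past the threshold (camera adjusted p = 0.34). Ctla4 (1.34 ± 0.17), Capg (1.01 ± 0.09), Tnfrsf4 (1.01 ± 0.15) and Tnfrsf18 (0.73 ± 0.13) rose, whereas the interleukin 2 receptor gene Il2ra (-0.52 ± 0.13), Lrrc32 (-1.33 ± 0.13) and Gpr83 (-1.81 ± 0.25) fell. Inhibitory receptors rose in 6 and fell in 1 of 13 genes (camera adjusted p = 0.00603; adjusted p = 0.755 with an estimated correlation). Cd200r1 (1.21 ± 0.20) and Entpd1 (0.69 ± 0.16) rose and Cd200 (-0.63 ± 0.10) fell, and 8 rose and 1 fell when adjusted over the list alone. This call was lost without effector library 1 (camera adjusted p = 0.0532).

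Of the apoptosis regulators 5 rose, 4 fell and 12 did not pass (camera adjusted p = 0.187). The protective gene Bcl2l1 rose by 0.82 ± 0.07 (edgeR adjusted p = 7.69e-04) and the executioner caspase gene Casp3 by 0.89, while Mcl1 (-0.32 ± 0.08), Casp8 (-0.38 ± 0.10) and the pro-apoptotic Bcl2l11 (-0.64 ± 0.17) fell with Bcl2. Homing receptors and chemokine receptors rose in 4 and fell in 6 of 24 genes (camera adjusted p = 0.706). Ccr10 (1.90 ± 0.49) and Ccr5 (2.70 ± 0.64) rose, whereas Ccr9 (-2.28 ± 0.43) and Itga4 (-0.60 ± 0.12) fell with Ccr7. Genes of NF-kB signalling and costimulation rose in 6 and fell in 1 of 20 (camera adjusted p = 0.0204; adjusted p = 0.755 with an estimated correlation), among them Tnfrsf1b (1.36 ± 0.22), with 8 and 1 when adjusted over the list alone. That call was lost without activated library 2 (camera adjusted p = 0.0758) and without effector library 1 (camera adjusted p = 0.287). Helper lineage and cytokine genes rose in 5 and fell in 1 of 16 (camera adjusted p = 0.0539), with Gata3 at 0.73, Il13 at 4.84 ± 0.74 and Il23r at 3.10. Il13 stood at 2.37 CPM and Il23r at 1.20 CPM in effector cells, so both rest on few counts.

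Glycolysis genes rose in 5 of 16, including Slc16a3 (1.14 ± 0.23), Tpi1 (0.86 ± 0.17) and Pkm (0.43 ± 0.09) (camera adjusted p = 0.00631; adjusted p = 0.755 with an estimated correlation), and 10 rose and 1 fell when adjusted over the list alone. Genes of protein folding and stress in the endoplasmic reticulum rose in 5 of 15, including Pdia6 (0.45 ± 0.07) and Hspa5 (0.40 ± 0.10) (camera adjusted p = 0.0149; adjusted p = 0.672 with an estimated correlation), with 8 and 1 when adjusted over the list alone. The proliferation list passed the set test (camera adjusted p = 0.00258; adjusted p = 0.897 with an estimated correlation), but Mcm6 (0.94 ± 0.18), a part of the replicative helicase, was the only 1 of 35 genes that rose. The effector libraries differed in this list: its summed expression was 1076 CPM in library 1 and 3562 CPM in library 2. Library 2 held more in the other wild type groups too. Their libraries 1 and 2 summed to 696 and 1173 CPM in naive and 759 and 1302 CPM in activated cells. Without effector library 2 the glycolysis and folding calls were lost (camera adjusted p = 0.0621 and 0.051) and the proliferation list leaned the other way (camera adjusted p = 0.865). Without activated library 1 the proliferation call was lost as well (camera adjusted p = 0.202).

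Several fixed lists did not pass: immediate early genes with 1 of 23 higher (Egr2, 0.76; camera adjusted p = 0.482), interferon response genes with 1 higher and 2 lower of 22 (Mx1, 0.76, and Ifit2, -0.43; camera adjusted p = 0.365), cholesterol synthesis (camera adjusted p = 0.714) and oxidative phosphorylation (camera adjusted p = 0.849) with none. The mean of the oxidative phosphorylation genes (0.01) and their median (-0.03) differed in sign. Of the sort markers 1 rose and 1 fell (camera adjusted p = 0.89), with a median of 0.04 and a mean of -0.59. Of the lists for other cell types, that of CD8 T cells passed and fell in 2 of 6 genes, Eomes (-3.91 ± 0.32) and Prf1 (-1.03 ± 0.25) (camera adjusted p = 0.0136; adjusted p = 0.672 with an estimated correlation). Other CD4 T cells also express Eomes and Prf1, and CD8 cells had been depleted before the sort. Without the depleted markers Cd8a and Cd8b1 the list had 4 genes, too few for the set test. B cell genes fell in 1 of 7 (Cd72, -0.95; camera adjusted p = 0.849) and plasma cell genes rose in 1 of 5 (Txndc5, 0.38; camera adjusted p = 0.0639). Natural killer cell (camera adjusted p = 0.777), myeloid (camera adjusted p = 0.405), dendritic cell (camera adjusted p = 0.706) and erythroid and platelet genes (camera adjusted p = 0.796) had no member past the threshold. The lists of the Myb family and of stromal and endothelial cells had 3 measured members each and were not tested as groups.

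The number of genes that separate effector from activated cells depended on single libraries. It was 894 without activated library 1, 449 without activated library 2 and 1028 without effector library 2. Of the genes named above as changed, 30 of 66 still passed without activated library 2. When either activated library was left out, a smaller share of the called genes was higher in effector cells than with all libraries. Lag3 passed in 8 and Ccr10 and Casp3 in 11 of 22 other settings. Of the 8 lists that passed by camera in this comparison 3 also passed by fry, those of naive and resting, folding and CD8 T cell genes.

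Effector cells were next compared with naive cells of the wild type, the ends of the path. Here 2888 genes were higher and 2549 lower in effector cells, 5437 in all, of which 2213 differed by at least 2-fold. Bcl2 fell by 3.18 ± 0.27 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.09e-04), Prdm1 rose by 3.63 ± 0.35 (edgeR adjusted p = 4.95e-04) and Il10 by 6.23 ± 0.89 (edgeR adjusted p = 0.00236). Of the effector Treg list 29 of 30 genes rose (camera adjusted p = 8.67e-11; adjusted p = 0.672 with an estimated correlation), among them Ccr8 (3.29 ± 0.28), Rora (2.12 ± 0.24) and Gata3 (1.19 ± 0.12). Of the naive and resting list 17 of 18 fell (camera adjusted p = 1.23e-10; adjusted p = 0.672 with an estimated correlation), among them Bach2 (-3.06 ± 0.23) and Foxp1 (-1.47 ± 0.12). These counts were the same when adjusted over the list alone. Without the sort genes they were 27 of 28 (camera adjusted p = 4.54e-10) and 16 of 17 (camera adjusted p = 5.99e-10). The largest rises included Klrg1 (4.36 ± 1.16), Nav2 (4.28 ± 0.94), Asb2, Il1r2 and the sort gene Tigit, and the largest falls were those of Igfbp4 (-9.58 ± 0.62), Sorcs2, Ly6c1, Treml2 and Dapk1. Asb2 passed in 11 and Klrg1 in 13 of 22 other settings, with log2 fold changes from 3.19 to 8.12 and from 3.51 to 6.34. Of the 7 lists that passed by camera in this comparison 5 also passed by fry.

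In the same comparison inhibitory receptors rose in 10 and fell in 1 of 13 genes (camera adjusted p = 5.91e-04), helper lineage and cytokine genes in 10 of 16 (camera adjusted p = 0.00156) and NF-kB and costimulation genes rose in 11 and fell in 1 of 20 (camera adjusted p = 0.0027). Each of these 3 lists had an adjusted p = 0.672 with an estimated correlation. Tnfrsf9 (1.79 ± 0.19) and Nt5e (1.52 ± 0.22), the gene of the adenosine-producing enzyme CD73, were examples. Glycolysis genes rose in 10 and fell in 2 of 16 (camera adjusted p = 0.0245; adjusted p = 0.755 with an estimated correlation). The 2 that fell were the enzyme gene Eno1 (-0.65 ± 0.13) and the glucose transporter gene Slc2a1 (-0.51 ± 0.11). The proliferation list passed the set test with 2 of 35 genes higher (camera adjusted p = 0.0172; adjusted p = 0.907 with an estimated correlation). Its call was lost without naive library 1 (camera adjusted p = 0.262) and without effector library 2 (camera adjusted p = 0.975), and that of glycolysis without naive library 2 (camera adjusted p = 0.0592) and without effector library 2 (camera adjusted p = 0.0771). Without naive library 1 the number of changed genes was 2938. Of the changed genes 53.1% were higher in effector cells, against 42.8% when the authors' log2 RPKM values were tested with limma.

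In the step from naive to activated cells in the wild type no single gene passed by edgeR, and gene lists passed only by camera with its preset correlation. By fry no list passed in this comparison (smallest adjusted p = 0.0532, naive and resting genes; 0.117 for the effector Treg list). With edgeR's quasi-likelihood test 0 of 13714 genes passed (smallest Benjamini-Hochberg adjusted p = 0.111), while 2917 had an unadjusted p under 0.05. DESeq2 called 1016 genes (620 higher, 396 lower), limma voom 0 and limma on the authors' log2 RPKM values 0. In the effector Treg list 29 of 30 genes had a positive log2 fold change, with a median of 1.36 (camera adjusted p = 2.05e-10; adjusted p = 0.672 with an estimated correlation). Of the naive and resting list 17 of 18 were negative, with a median of -0.82 (camera adjusted p = 5.63e-08; adjusted p = 0.672 with an estimated correlation). Adjusted over the list alone, 14 effector genes rose and 13 naive genes fell. Without the sort genes 27 of 28 effector genes were positive (camera adjusted p = 1.03e-09) and 16 of 17 naive genes negative (camera adjusted p = 1.65e-07). Ccr7 had a log2 fold change of -0.86 ± 0.17 (edgeR adjusted p = 0.111), Lef1 of -0.83 ± 0.14 (edgeR adjusted p = 0.111), Bcl2 of -0.85 ± 0.25 (edgeR adjusted p = 0.131) and Prdm1 of 1.06 ± 0.33 (edgeR adjusted p = 0.143).

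In this comparison all 13 inhibitory receptor genes had positive values (camera adjusted p = 1.17e-04; 5 rose when adjusted over the list alone), and so did 14 of 16 helper lineage and cytokine genes (camera adjusted p = 6.44e-04) and 17 of 20 NF-kB and costimulation genes (camera adjusted p = 0.00142). These 3 lists had an adjusted p = 0.672 with an estimated correlation. Homing genes leaned upward (camera adjusted p = 0.00779; adjusted p = 0.755 with an estimated correlation), with 14 higher and 6 lower when adjusted over the list alone. Cholesterol synthesis genes were negative in 18 of 19 (median -0.17; camera adjusted p = 0.00603; adjusted p = 0.769 with an estimated correlation). Oxidative phosphorylation genes were negative in 24 of 25 (median -0.11; camera adjusted p = 0.00674; adjusted p = 0.803 with an estimated correlation), a call lost without activated library 1 (camera adjusted p = 0.16). The dendritic cell list leaned upward (camera adjusted p = 0.0193; adjusted p = 0.748 with an estimated correlation). It includes Cd74 and Irf8, which activated T cells express too, and its call was lost without naive library 1 (camera adjusted p = 0.128) and without activated library 2 (camera adjusted p = 0.0879).

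Naive library 2 decided the count of 0. Without it, an alternative in which naive library 1 is assumed to vary like the other groups, 888 genes passed, 624 higher and 264 lower in activated cells. Among them were the chemokine receptor genes Cxcr6 (4.39 ± 0.53; edgeR adjusted p = 0.0173) and Cxcr3 (3.50 ± 0.36; edgeR adjusted p = 0.0123), the transcription factor gene Tbx21 (3.61 ± 0.22; edgeR adjusted p = 0.00211), Ccl5 (4.70 ± 0.60; edgeR adjusted p = 0.019) and Prdm1 (1.61 ± 0.29; edgeR adjusted p = 0.0294). Ccr7 fell by 1.08 ± 0.15 (edgeR adjusted p = 0.0142). Of the effector Treg list 14 of 30 rose, of the homing list 12 rose and 1 fell of 24, and of the naive list 5 of 18 fell.

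In the cells labelled Myb knockout single genes passed on activation, but these calls depended on single libraries. Without naive library 2, or without both libraries with Y-linked reads, a compared group keeps a single library. The spread then comes from the other groups, among them wild type naive library 2. The calls were lost in these settings, but 0 of the 26 genes named here as changed reversed direction. Irf4 rose by 1.08 ± 0.13 on the log2 scale, from 52.3 ± 9.91 to 110 ± 1.37 CPM (SD, n = 2; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00418). Cd44, an adhesion receptor of activated T cells, rose by 1.56 ± 0.18, Ccr8 by 2.26 ± 0.30 (edgeR adjusted p = 0.00595) and Il10 by 5.60 ± 1.25 (edgeR adjusted p = 0.0268). The transcription factor gene Lef1 fell by 1.23 ± 0.15 (edgeR adjusted p = 0.00409), and S1pr1, whose receptor guides T cells out of lymph nodes, by 1.73 ± 0.24. Of 13714 genes 1578 rose and 845 fell, 2423 in all, and 1063 of these changed by at least 2-fold. The 5 largest rises were those of Tox2 (6.24 ± 1.58), Ttn, S100a4 (5.77 ± 1.47), Il1r2 (5.74 ± 1.41) and the sort gene Tigit, and the 5 largest falls those of Ly6c1 (-2.45 ± 0.39), Igfbp4 (-2.13 ± 0.38), Dapk1, Itgb3 and Gpr146. Tox2, Ttn, S100a4, Il1r2 and Tigit each passed in only 10 of 22 other settings.

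Of the effector Treg list 20 of 30 genes rose and 0 fell (camera adjusted p = 1.23e-10; adjusted p = 0.672 with an estimated correlation), and 22 rose when adjusted over the list alone. Of the naive and resting list 10 of 18 fell and 0 rose (camera adjusted p = 8.41e-07; adjusted p = 0.672 with an estimated correlation), and 16 fell when adjusted over the list alone. Without the sort genes 18 of 28 rose (camera adjusted p = 8.16e-10) and 9 of 17 fell (camera adjusted p = 2.09e-06). Treg identity genes rose in 9 of 15 (camera adjusted p = 4.42e-04), among them Ikzf2 (0.86 ± 0.14), Izumo1r (1.25 ± 0.20) and Tnfrsf9 (1.24 ± 0.19). Inhibitory receptors rose in 9 of 13 (camera adjusted p = 1.71e-05), among them Nt5e (1.52 ± 0.22) and Cd160 (1.76 ± 0.20), NF-kB and costimulation genes in 10 of 20 (camera adjusted p = 8.52e-04), and helper lineage and cytokine genes in 8 of 16 (camera adjusted p = 1.18e-04), among them Ifng (5.08 ± 0.93). These 4 lists had an adjusted p = 0.672 with an estimated correlation. Homing genes rose in 11 and fell in 6 of 24 (camera adjusted p = 0.0117; adjusted p = 0.755 with an estimated correlation), with Ccr6 (2.22 ± 0.30) higher and S1pr4 (-0.67 ± 0.07) lower.

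Cholesterol synthesis genes fell in 2 of 19 (camera adjusted p = 0.00108; adjusted p = 0.755 with an estimated correlation) and interferon response genes in 5 of 22, including Oasl1 (-1.44 ± 0.35) and Ifit2 (-0.47 ± 0.08) (camera adjusted p = 0.00643; adjusted p = 0.803 with an estimated correlation). None of the 25 oxidative phosphorylation genes passed, and the call of that list (camera adjusted p = 0.0323; adjusted p = 0.878 with an estimated correlation) was lost without naive library 1 (camera adjusted p = 0.202) and without activated library 2 (camera adjusted p = 0.132). The count of changed genes rested on single libraries: it was 437 without naive library 1, 2 without naive library 2 and 500 without activated library 1. Naive library 1 and activated library 1 held reads of Y-linked genes although the donors are labelled female. Without both of them each group labelled Myb knockout keeps a single library, and the spread comes from the wild type groups, naive library 2 included. The calls were lost in that setting, which cannot tell an effect of the libraries with Y-linked reads from the loss of replication. Of the changed genes 65.1% were higher, against 52.7% with limma on the authors' log2 RPKM values. Of the 10 lists that passed by camera in this comparison 6 also passed by fry. No list of another cell type passed by camera. B cell genes rose in 3 of 7 (camera adjusted p = 0.166; fry adjusted p = 0.0298) and dendritic cell genes in 3 of 8 (camera adjusted p = 0.0589). CD8 T cell genes rose in 2 and fell in 2 of 6 (camera adjusted p = 0.967). The plasma cell, natural killer cell and myeloid lists each had 1 gene higher.

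Whether activation differed between the genotypes was tested as an interaction. No gene passed edgeR's quasi-likelihood test (0 of 13714, smallest Benjamini-Hochberg adjusted p = 0.0821), while DESeq2 called 23 and limma voom 0. By edgeR 691 genes (5.04%) had an unadjusted p under 0.05, about the share that no difference would give. The log2 fold changes of activation in the 2 genotypes correlated across genes at r = 0.775 (Spearman 0.751), with no library in common. By edgeR no gene was called in both because the wild type comparison called none, while DESeq2 called 898 genes in both. When naive library 2 was left out, 557 genes rose and 203 fell in both genotypes, against 72.9 and 16.6 for independent lists, and 0 moved in opposite directions. The interaction called 13 genes without naive library 1 of the wild type and 3 without activated library 2 labelled Myb knockout.

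Naive cells labelled Myb knockout differed from naive wild type cells in few genes. The pseudogene Rps15a-ps8 (GRCm38 chromosome 4, start 53791031, end 53791468) fell by 6.44 ± 0.25, from 150 ± 8.13 to 1.70 ± 0.161 CPM (SD, n = 2; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 7.44e-05). It is a copy of the ribosomal protein gene Rps15a, so reads can be divided between copies and its level is uncertain. Map7, a microtubule-associated protein gene at chromosome 10, start 20148920, end 20281590, fell by 1.33 ± 0.15 (edgeR adjusted p = 0.0372). H60b, a ligand gene of the receptor NKG2D at chromosome 10, start 22273474, end 22288849, rose by 3.89 ± 0.34 (edgeR adjusted p = 0.00969), from 0.633 and 0.876 CPM in the wild type to 9.97 and 12.4 CPM. With the transcribed loci C78197 (-2.04 ± 0.22) and 1700021A07Rik, which fell, these are the 5 of 13714 genes that passed, 1 higher and 4 lower. H60b, C78197 and 1700021A07Rik were named after their values were seen. An unadjusted p under 0.05 was seen for 1150 genes, and DESeq2 called 231 genes and limma voom 1.

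Several lists leaned toward lower expression in these naive cells, although no member of any list passed edgeR's test. By DESeq2 the list members Rora (adjusted p = 7.08e-04), Cxcr3 (adjusted p = 6.31e-04) and Cd69 (adjusted p = 0.00238) passed. Of the effector Treg list 28 of 30 genes were negative, with a median of -1.16 (camera adjusted p = 6.06e-13; adjusted p = 0.672 with an estimated correlation), and 6 fell when adjusted over the list alone. Without the sort genes 26 of 28 were negative (camera adjusted p = 1.06e-11). Rora stood at -1.30 ± 0.26 (edgeR adjusted p = 0.304) and Irf4 at -0.48 ± 0.13 (edgeR adjusted p = 0.448). Homing genes (median -0.85; camera adjusted p = 1.02e-07; 7 lower when adjusted over the list alone), inhibitory receptors (median -0.44; camera adjusted p = 4.30e-05) and helper lineage and cytokine genes (median -0.88; camera adjusted p = 5.91e-04) leaned the same way, each with an adjusted p = 0.672 with an estimated correlation. Naive library 2 of the wild type held more of these transcripts than naive library 1: Cxcr3 stood at 13.9 CPM in library 1 and 72.5 CPM in library 2. Without library 2 the helper lineage call was lost (camera adjusted p = 0.112).

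Proliferation genes (median -1.26; camera adjusted p = 0.00955; adjusted p = 0.907 with an estimated correlation) and Treg identity genes (median -0.17; camera adjusted p = 0.0172; adjusted p = 0.755 with an estimated correlation) were lower, and so was the plasma cell list (camera adjusted p = 0.0101; adjusted p = 0.672 with an estimated correlation), in which Txndc5 (-0.30 ± 0.09) had the smallest adjusted p (edgeR adjusted p = 0.448) but not the largest difference. Immediate early genes were higher (median 0.43; camera adjusted p = 0.0204; adjusted p = 0.878 with an estimated correlation), with Cd69 at 0.75 ± 0.18. Their summed expression was 4594 CPM in naive library 2 labelled Myb knockout and 2032 CPM in library 1. The proliferation call was lost without wild type library 2 (camera adjusted p = 0.923) and without library 1 labelled Myb knockout (camera adjusted p = 0.0732), which also ended the plasma cell call (camera adjusted p = 0.0795). The Treg identity call was lost without wild type library 1 (camera adjusted p = 0.0849) and without library 2 labelled Myb knockout (camera adjusted p = 0.424). The immediate early call was lost in both of these settings (camera adjusted p = 0.303 and 0.585, the second in the opposite direction) and without either effector library (camera adjusted p = 0.0708 and 0.0709).

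The count of 5 genes in naive cells depended on single libraries. It was 216 without wild type naive library 1 (7 higher, 209 lower) and 1 without naive library 2 or without either naive library labelled Myb knockout. It was 2 without any one of the 4 activated libraries. Map7 passed in 10 and C78197 and 1700021A07Rik in 9 of the other settings. Leaving out both libraries with Y-linked reads leaves a single naive library labelled Myb knockout. Most of the 5 calls were then lost, and the calls were mostly higher instead of lower. None of the 8 lists that passed by camera passed by fry (adjusted p = 0.0532 to 0.727).

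In activated cells, 10 of 13714 genes differed between the libraries labelled Myb knockout and the wild type. Tns1, which encodes the focal adhesion protein tensin 1, rose by 1.09 ± 0.11, from 76.2 ± 7.71 to 163 ± 1.47 CPM (SD, n = 2; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.018). Fsd1l rose by 1.23 ± 0.10 (edgeR adjusted p = 0.00491) and the creatine kinase gene Ckb by 1.14 ± 0.14 (edgeR adjusted p = 0.0366). S1pr4, a sphingosine 1-phosphate receptor gene, fell by 0.56 ± 0.07 (edgeR adjusted p = 0.0366), from 179 ± 4.89 to 121 ± 5.99 CPM. The glycosyltransferase gene B3gnt5 (-1.32 ± 0.14), Gmfg (-1.15 ± 0.14), the phosphodiesterase gene Pde2a (-0.94 ± 0.11), and the lipid transfer protein gene Osbpl5 (-0.86 ± 0.10) fell too. Rps15a-ps8 fell by 6.23 ± 0.26 (edgeR adjusted p = 1.19e-04) and H60b rose by 4.06 ± 0.33 (edgeR adjusted p = 0.00491), as in naive cells. Fsd1l lies close to Rps15a-ps8 on chromosome 4 (start 53631383, end 53707009), and its log2 fold change in naive cells did not pass (-0.18 ± 0.10; edgeR adjusted p = 0.71). Of the 10 genes 4 were higher and 6 lower, 7 changed by at least 2-fold, and 1727 genes had an unadjusted p under 0.05. DESeq2 called 277 genes and limma voom 3.

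Key genes of effector differentiation did not pass edgeR's test in this comparison: Prdm1 stood at -0.77 ± 0.34 (edgeR adjusted p = 0.418), Bcl2 at 0.32 ± 0.25 (edgeR adjusted p = 0.669), Irf4 at 0.12 ± 0.13 (edgeR adjusted p = 0.76) and Klrg1 at -2.15 ± 1.15 (edgeR adjusted p = 0.519). Over 22 other settings Prdm1 ranged from -1.18 to -0.42, Bcl2 from 0.18 to 0.48 and Klrg1 from -4.47 to -1.20, and none of them passed. Interferon response genes were lower as a group, 19 of 22 negative with a median of -0.40 (camera adjusted p = 1.18e-04; adjusted p = 0.755 with an estimated correlation), and 3 fell when adjusted over the list alone. Oas1a (-1.02 ± 0.19; edgeR adjusted p = 0.121) and Mx2 (-1.23 ± 0.29; edgeR adjusted p = 0.17) were examples that did not pass by edgeR, and both passed by DESeq2 (adjusted p = 5.71e-04 and 0.0141). Homing genes leaned lower (median -0.29; camera adjusted p = 0.0149; adjusted p = 0.755 with an estimated correlation), with S1pr4 past the threshold and 7 lower and 1 higher when adjusted over the list alone. Immediate early genes leaned higher (median 0.55; camera adjusted p = 0.0218; adjusted p = 0.878 with an estimated correlation). Their summed expression was 5903 CPM in activated library 2 labelled Myb knockout and 2388 CPM in library 1. The interferon call was lost without wild type activated library 2 (camera adjusted p = 0.0738) and the homing call without activated library 2 labelled Myb knockout (camera adjusted p = 0.0739). Each of these 2 libraries also decided the immediate early call (camera adjusted p = 0.114 and 0.807, the second in the opposite direction).

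The number of calls in activated cells, 10 with all libraries, changed with the libraries fitted. Leaving out 1 library of a compared group leaves a lone library, so fewer calls there can come from lost replication alone. The balance of directions moved too. Most calls were higher without activated library 2 labelled Myb knockout, and most were lower when either naive library of the wild type was left out. Without activated library 1 of the wild type 1 gene passed and without library 2, 2 genes. Without activated library 1 labelled Myb knockout 3 genes passed and without library 2, 24 genes. Leaving out a naive library gave 23 genes for either one of the wild type and 4 for either one labelled Myb knockout, and leaving out effector library 1 or 2 gave 38 and 37. S1pr4, Gmfg and Osbpl5 passed in 12 of 22 other settings. None of the 3 lists that passed by camera passed by fry (adjusted p = 0.236 to 0.646).

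The same genes were compared across naive and activated cells, 2 comparisons without a library in common. H60b rose in both, against 2.92e-04 expected by chance (two-sided Fisher exact test, Benjamini-Hochberg adjusted p = 0.0035), and Rps15a-ps8 fell in both, against 0.00175 expected (adjusted p = 0.0105 by the same test). No gene moved in opposite directions. The log2 fold changes correlated across genes at r = 0.417 (Spearman 0.352). The number of shared genes was 2, and it was 1 without wild type naive library 2, either wild type activated library or either naive library labelled Myb knockout. Without wild type naive library 1 the number was 13 and without effector library 1 it was 4.

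H60b and Map7 both lie close to Myb on chromosome 10. Within 10 Mb of Myb, 67 genes were tested, and 11 of them differed in the same direction in naive and activated cells with an unadjusted p under 0.05 in both. Besides H60b and Map7, Sf3b5 stood at -0.50 in naive and -0.49 in activated cells, Phactr2 at 0.48 and 0.75, and Ect2l at 2.04 and 2.15. Of the 11 genes 5 were higher and 6 lower. The counting strand is not stated, so overlapping and antisense genes in this region are uncertain.

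**Figure D3:**
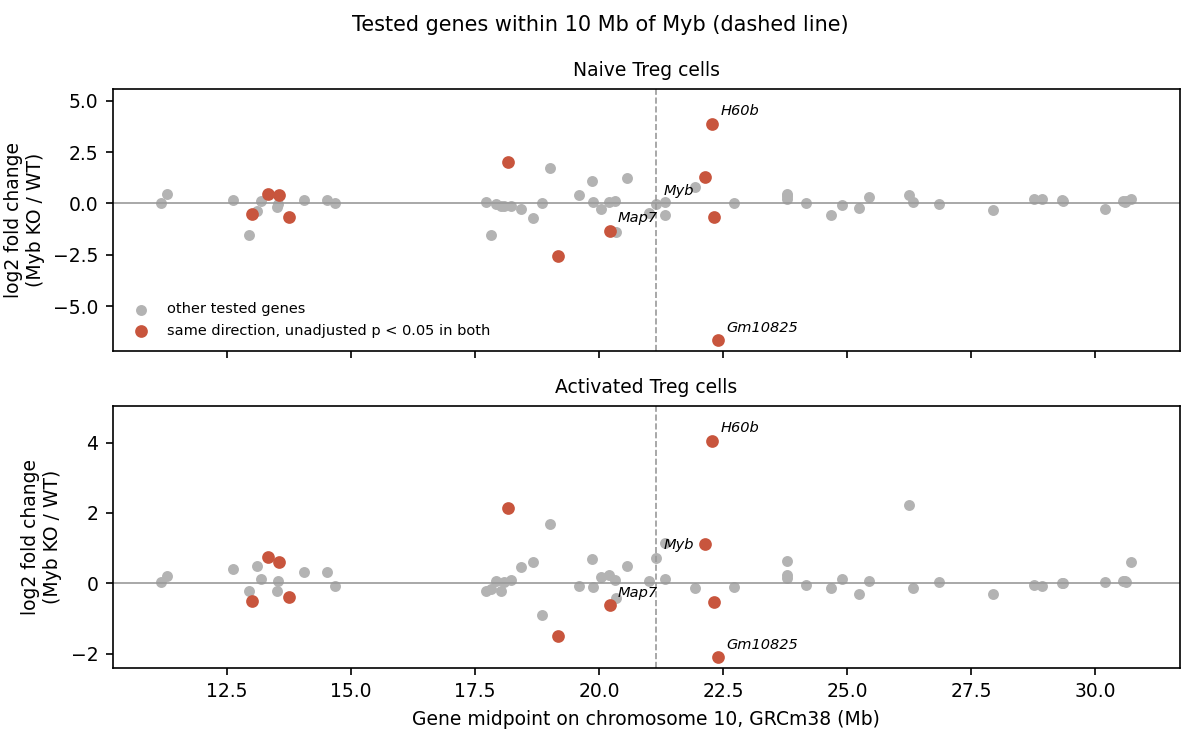
Log2 fold change (labelled Myb knockout against wild type) of the 67 tested genes within 10 Mb of Myb on GRCm38 chromosome 10, by position in Mb, in naive and in activated cells, with 1 point per gene. The 11 genes in red differed in the same direction with an unadjusted p under 0.05 in both populations, and the line marks Myb. Gm10825 and Gm20139 are among the 11 and rest on few counts.

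Whether genes of the effector path differ in activated cells labelled Myb knockout was tested with the 200 genes most raised and the 200 most lowered in effector against naive wild type cells, a comparison that shares no library with this one. Of the raised genes 148 of 200 were lower, with a median log2 fold change of -0.53 (camera p = 7.03e-06, Benjamini-Hochberg adjusted p = 1.41e-05; p = 0.442 with an estimated correlation). Of the lowered genes 131 of 200 were higher, with a median of 0.21 (camera p = 0.00129; p = 0.508 with an estimated correlation). Across all genes the 2 sets of log2 fold changes correlated at r = -0.233 (Spearman -0.243). Of the 10 genes called in activated cells, B3gnt5, Gmfg and Osbpl5 were lower in these cells and higher in effector cells (1.26 expected; two-sided Fisher exact p = 0.112), and Fsd1l and Tns1 were higher here and lower in effector cells (0.743 expected; p = 0.159 by the same test). S1pr4 and Rps15a-ps8 were lower in both. The rise of Gmfg in effector cells passed in 8 of 22 other settings. At this threshold the number in opposite directions did not pass the test. At the looser adjusted p under 0.1 there were 11 lower here and higher in effector cells (6.39 expected; unadjusted two-sided Fisher exact p = 0.0405) and 13 higher here and lower in effector cells (4.57 expected; unadjusted p = 6.71e-05 by the same test).

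The shift of the effector genes rested on single libraries. Without activated library 2 labelled Myb knockout the raised genes had a median of -0.09 and the lowered genes of -0.08, and without activated library 1 of the wild type the lowered genes had a median of -0.09. Over all settings that left out 1 library the medians ran from -1.44 to -0.09 for the raised and from -0.09 to 0.56 for the lowered genes.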

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

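The tests of explanations in this part, the tests of lists without sort genes, and the settings that left out the libraries with Y-linked reads, were chosen after the results were seen, whereas the interaction tests were planned.

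Activation from naive to activated cells differed between the genotypes for 6 gene lists by the interaction test, although no single gene passed edgeR's test; DESeq2 called 23 genes. The change on activation was more positive in the cells labelled Myb knockout for the Treg identity list (camera adjusted p = 1.12e-04; 15 of 15 genes), the effector Treg list (camera adjusted p = 1.42e-05; 26 of 30 genes), inhibitory receptors (camera adjusted p = 2.77e-04; 12 of 13), helper lineage and cytokine genes (camera adjusted p = 0.0218; 11 of 16) and homing genes (camera adjusted p = 0.043; 16 of 24). It was more negative for interferon response genes (camera adjusted p = 0.00585; 18 of 22). The medians of the interaction were 0.31 for Treg identity, 0.82 for effector Treg, 0.77 for inhibitory receptors and -0.36 for interferon response genes. Median differences between the genotypes were -1.16 in naive and -0.22 in activated cells for effector Treg genes. They were -0.44 and 0.08 for inhibitory receptors, -0.17 and 0.02 for Treg identity, -0.88 and -0.11 for helper lineage and -0.85 and -0.29 for homing genes. The more positive change in these lists thus went with lower values in naive cells labelled Myb knockout, not with clearly higher values in activated ones. Examples of single genes that did not pass by edgeR were Ctla4 (0.68 ± 0.23; edgeR adjusted p = 0.88), Cxcr3 (3.50 ± 1.12; edgeR adjusted p = 0.88) and Irf8 (1.01 ± 0.14; edgeR adjusted p = 0.246). Irf8 passed by DESeq2 (adjusted p = 6.36e-04) and in 3 of 22 other settings in all, and Cxcr3 in 1. With an estimated correlation none of the 6 lists passed (adjusted p = 0.672 to 0.803), and none passed by fry (adjusted p = 0.164 to 0.642). Sort genes are members of 4 of these lists, and without them the Treg identity (camera adjusted p = 6.18e-05), effector Treg (4.58e-05), inhibitory receptor (6.32e-04) and homing lists (0.0263) still passed.

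Single libraries decided several of these calls. Without wild type naive library 2 the effector Treg (camera adjusted p = 0.062), homing (0.169) and helper lineage calls (0.499) were lost, while the Treg identity (4.44e-04), inhibitory receptor (0.0398) and interferon lists (4.74e-05) still passed. The interferon call was lost without wild type naive library 1 (camera adjusted p = 0.23), without wild type activated library 2 (0.387) and without activated library 1 labelled Myb knockout (0.0579). The helper lineage call was lost without wild type activated library 2 (camera adjusted p = 0.055) and without activated library 1 or 2 labelled Myb knockout (0.0535 and 0.0524). The homing call was lost without wild type activated library 1 or 2 (camera adjusted p = 0.0687 and 0.0523), effector library 1 or 2 (0.097 and 0.0957), naive library 2 labelled Myb knockout (0.215) and activated library 1 or 2 labelled Myb knockout (0.117 and 0.119). Without both libraries with Y-linked reads the helper lineage (camera adjusted p = 0.0854) and interferon calls (0.156) were lost. With wild type naive library 2 left out too, the effector Treg (camera adjusted p = 0.163), inhibitory receptor (0.237) and helper lineage calls (0.317) were lost.

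Wild type naive library 2 lies between naive library 1 and the activated libraries. An exchange of labels with activated library 2 is argued against by that library, which lies at 0.698 of the way from naive to activated library 1 for genes raised on activation of the cells labelled Myb knockout. A shift shared by all libraries numbered 2 is argued against as well, since naive library 2 labelled Myb knockout lies at -0.0385 of the way for genes raised in effector against naive wild type cells. Activated cells among the sorted naive cells are a candidate explanation. Genes raised on activation of the cells labelled Myb knockout place the library at 0.377 and lowered genes at 0.402 of the way. The difference is 0.0244. In all these placements genes were kept only where the start and the end of the way themselves differed at least 2-fold. Such a choice can draw a further library inward for raised and lowered genes alike, so the small difference is weak support. A partial activation of all naive cells in this pool would give the same values and stays open, as does a shift in only some of the libraries numbered 2: activated library 2 labelled Myb knockout lies short of activated library 1, at 0.612 of the way for raised and 0.799 for lowered genes.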

How the results depend on the processing

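The planned settings were joined, after the data were seen, by limma on the log2 RPKM values, by removal of ribosomal RNA genes, by lists without sort genes, and by removal of the libraries with Y-linked reads, alone or with wild type naive library 2. Groups of 2 leave a lone library when 1 is left out, which is then assumed to vary like the other groups. The count of genes past the threshold for effector against activated cells (1840) ranged from 1408 to 2181 under the planned choices of scaling, test, filter, libraries fitted and block. The causes of the changes were not tested. Depth limits genes below about 0.213 CPM, the value of 3 counts in the smallest library.

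The Wald test of DESeq2 called 1016 genes for activation in the wild type, 231 and 277 for the genotypes in naive and activated cells, and 23 for the interaction. With it 52 genes were shared between the genotype comparisons, 150 between effector and genotype differences, and 898 between activation in the 2 genotypes. Limma voom gave 1 and 3 genes for the genotypes in naive and activated cells and overlaps of 1 and 2. Without a filter on low counts these were 12 and 61 genes, 3 for the interaction and an overlap of 33 with the effector differences. A CPM of at least 5 in 2 libraries left 2 genes in naive cells. With only the groups compared there were 3476 genes for effector against naive cells, 3 and 39 for the genotypes and an overlap of 14. Limma on the log2 RPKM values gave 3 and 31 genes for the genotypes and an overlap of 15. At a fold of at least 2, 574, 2213 and 1063 genes passed for effector against activated, effector against naive and activation of cells labelled Myb knockout. At an adjusted p under 0.1 the genotype comparisons shared 4 genes, and effector and genotype differences shared 24. With an estimated correlation 0 and with fry 23 of 161 list tests passed. With sort genes left out of the lists 53 of 147 passed, 50 of them among the 51; the CD8 T cell list became too short to test.

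Without both libraries with Y-linked reads 12 and 19 genes passed between the genotypes in naive and activated cells, and 11 were shared. For activation of cells labelled Myb knockout 0 passed. Each group labelled Myb knockout is then a single library, and both are numbered 2. Most genotype calls made with all libraries were lost, and most of those that passed were higher. Immediate early genes summed to more CPM in these libraries than in any other, 4594 in naive and 5903 in activated cells. A difference of genotype in the shared genes cannot be told apart from a trait common to these libraries. With wild type naive library 2 left out too, activation gave 585 genes in the wild type, 423 in cells labelled Myb knockout and 312 in both, and the genotypes differed in 23 genes in activated cells, with 6 shared.

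With the replicate number as a block 25 genes differed between the genotypes in activated cells, against 10 without it, and 12 were shared with the effector differences, against 5. The block ended the homing interaction (camera adjusted p = 0.0791), and 50 of the 51 list calls were also made with it. Of the 26 named genes called in activation of cells labelled Myb knockout 21 were called with the block; Tox2, Ttn, S100a4, Il1r2 and Tigit were not. The labels do not say that the numbers pair the libraries. Deviations of libraries with the same number correlated between -0.194 and 0.583 over the 10 pairs of groups. Pairs within the wild type gave 0.137, 0.275 and 0.583, and the pair labelled Myb knockout gave 0.266. The value of -0.194 was between wild type naive cells and activated cells labelled Myb knockout. The erythroid gene Hba-a2 was counted only in libraries numbered 2. A trait shared by libraries of the same number is thus possible, and the fit without a block ignores it.

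Leaving out 1 library at a time gave 0 to 888 genes for activation in the wild type, 449 to 2047 for effector against activated cells, 2938 to 5522 for effector against naive cells, 1 to 216 and 1 to 38 for the genotypes in naive and activated cells, 2 to 2820 for activation of cells labelled Myb knockout and 0 to 13 for the interaction. List calls ranged from 50 to 64, and 28 of the 51 were made in every setting that tested them other than an estimated correlation and fry. Overlaps ranged from 1 to 13 for the genotype, 0 to 25 with the effector differences and 0 to 760 for activation. The median of the genes raised in effector cells ranged from -1.44 to -0.0873, smallest in size without activated library 2 labelled Myb knockout, and that of the lowered genes from -0.0872 to 0.56, reversed at -0.0872 without wild type activated library 1 and at -0.0826 without activated library 2 labelled Myb knockout. Of the named genes that had passed, 0 changed direction under any setting.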

Other observations

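The tests of explanations in this part were chosen after the results were seen.

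Several genes known as markers of other blood cells differed between naive and effector Treg cells. Pecam1, an adhesion receptor best known from endothelium, fell by 1.68 ± 0.11 on the log2 scale between naive and effector wild type cells (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.03e-04), from 299 and 236 to 81.2 and 85.7 CPM. Cd74, the invariant chain of class II antigen presentation, rose by 2.23 ± 0.47 (edgeR adjusted p = 0.0122), from 32.7 ± 10.9 to 153 ± 7.31 CPM (SD, n = 2), while the class II gene H2-Ab1 stayed at or under 3.55 CPM in each library. The cytotoxic granule gene Nkg7 rose by 1.71 ± 0.36 (edgeR adjusted p = 0.00917) and the perforin gene Prf1 fell by 1.91 ± 0.25 (edgeR adjusted p = 6.48e-04). The transcription factor gene Irf8 rose by 0.56 ± 0.10 (edgeR adjusted p = 0.00244) and Cebpb by 2.26 ± 0.45 (edgeR adjusted p = 0.00558). The B cell gene Cd22 stood at 0.668 and 10.3 CPM in naive and 47.2 and 35.2 CPM in effector libraries and did not pass (edgeR adjusted p = 0.0735), and the B cell gene Ms4a1 stayed at or under 0.545 CPM in each library.

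Transcripts of red blood cells, immediate early genes and cell cycle genes differed between libraries of a group. The erythroid and platelet list summed to 2.02 to 3.58 CPM in the 5 libraries numbered 1, and to 57.0, 53.3 and 42.4 CPM in the naive, activated and effector libraries numbered 2 of the wild type and 9.83 and 10.2 CPM in the naive and activated ones labelled Myb knockout. Immediate early genes summed to 4594 and 5903 CPM in naive and activated library 2 labelled Myb knockout, against 2030 to 3048 CPM in the other 8 libraries. The proliferation gene Mki67 stood at 132 CPM in effector library 1 and 597 CPM in effector library 2. The proliferation list summed to more CPM in library 2 than in library 1 of each wild type group. Libraries 1 and 2 labelled Myb knockout summed to 695 and 667 CPM in naive and 742 and 837 CPM in activated cells. Ctss made up most of the myeloid list, with 288 to 378 CPM in each library. The causes of these differences were not tested.

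Genes were counted here when they differed between the genotypes in the same direction in naive and in activated cells, with an unadjusted p under 0.05 in both. Of 13218 tested genes farther than 10 Mb from Myb, 311 (2.35%) did so. Within 10 Mb it was 9 of 65 (13.8%) when Map7 and H60b, through which the pattern was seen, were left out (Fisher exact p = 2.38e-05). The 9 include Gm10825 and Gm20139, which rest on few counts. E030030I06Rik, C920009B18Rik and Gm10825 lie close to H60b, and the counting strand is not stated. The test takes neighbouring genes as independent, so its p may be too small. Chromosome around Myb that came along with the floxed allele from another strain is a candidate explanation of these neighbours. An action of Myb loss on its neighbours cannot be told apart from it, because the 11 genes moved both ways, 5 of them higher, which either allows. For Rps15a-ps8 on another chromosome, reads moved between the copies of Rps15a cannot be told apart from a change in expression. The other copies together gained 145% of its loss in naive and 179% in activated cells, but 73.5% in naive cells without wild type library 2 and up to 232% in activated cells with 1 library left out, and Rps15a-ps6 stood lower as well, at 97.2 CPM against 130 CPM.

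Reads of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were found in naive library 1 (536 counts) and activated library 1 (2336 counts) labelled Myb knockout, whose donors are labelled female, with Ddx3y at 13.0 and 67.2 CPM there and at 0 CPM in the other 8 libraries. Male cells in the pooled sorts are a candidate source: Xist in activated library 1 was 0.527 of that in library 2, below the 0.874 to 1.07 of the wild type pairs, and the ratios of naive to activated library 1 had a median of 0.183 and a spread of 1.86-fold over the 4 genes. The Xist ratio of 0.906 in the naive pair lies within that span and decides nothing. Foxp3 in activated library 1 was 0.927 of that in library 2, whereas in each other group library 1 held more Foxp3 than library 2. That Foxp3 was reduced less than Xist argues against all of the male cells being other than Treg cells. Some of them may have been. The sex of the donors, the sorts that were pooled and the genotype of such cells stay open.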
